A study of Homo sapiens with 8 samples.

How the data were processed

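RNA from MCF-7 cells, an established oestrogen receptor positive breast cancer line, was sequenced in 8 libraries: 4 from untreated cells and 4 from cells given 6 µM 6-thioguanine for 48 h. 6-thioguanine is a thiopurine that cells turn into thioguanine nucleotides, which are built into DNA. The groups and the replicate numbers came from the sample titles and the drug treatment label. The labels name no vehicle for the untreated cells and do not say whether the libraries of a group came from separate cultures, so every p-value measures only the spread between these samples, which may be technical.

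The deposited tables give the authors' TPM (transcript abundance scaled to a fixed sum per library) for each of 178136 human Ensembl transcripts, per the file headers, and each library sums to 1000000 TPM. Per the submitters' processing notes, Bowtie 0.12.2 was used, and the same notes list the mouse builds mm10 and GRCm38. The transcript identifiers in the tables are human, so these builds cannot describe the values used here. The program that estimated the TPM values and its annotation are not given in the sources used here. TPM keeps no depth, so the depth of each library is unknown and no counting interval or detection floor is given.

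Transcripts were matched by identifier, without the version number, to GENCODE release 29 on the GRCh38 human genome. Of all transcripts, 162453 matched (159513 with the same version) and 15683 did not, and the latter held 2.39% to 2.57% of the TPM of a library. The unmatched transcripts were not assigned to genes, so the level of a gene to which some of them belong would be too low here. TPM values were summed over the transcripts of a gene, which gave 35075 genes and, with the gene of highest mean kept for each symbol, 35055. The tables hold 95.8% of the protein-coding transcripts of GENCODE 29 and 0.905% of its lincRNA transcripts, so long non-coding RNAs were not analysed here. Symbols and coordinates are those of GENCODE 29.

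Genes with at least 1 TPM in at least 4 libraries were tested with limma 3.58.1 in R 4.3.3 (linear model of log2(TPM + 1) on group, empirical Bayes with trend and robust options), and p-values were adjusted over all tested genes by the Benjamini-Hochberg method. A gene counts as changed at an adjusted p under 0.05. Every log2 fold change is on the log2(TPM + 1) scale, which understates the change of genes at low TPM. Means and SDs are of TPM over 4 libraries per group. DNMT1 also had an exact two-sided permutation test over the 70 ways to split the libraries.

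Before the data were examined, 27 gene lists were fixed, together with the tests, the alternatives and the rule for the genes to name. The lists cover the DNA methylation machinery, p53 targets, pro-apoptotic and anti-apoptotic genes, G1/S and replication genes, G2/M genes, G1 regulators, mismatch repair, DNA damage signalling, thiopurine handling, purine synthesis, the integrated stress and unfolded protein responses, oestrogen response, interferon response, cancer-testis genes, inflammatory secretory genes, ribosome biogenesis, replication histones, cholesterol synthesis, hypoxia and glycolysis, the nuclear-encoded and mitochondrially encoded respiratory chain, ribosomal proteins, housekeeping genes, luminal markers, basal or mesenchymal markers, and blood or endothelial markers. Some genes are in more than 1 list. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists with at least 3 tested members. Each camera test was repeated with an estimated correlation, and fry was run beside it. Fry asks whether the members of a list move on balance, without comparing them with other genes.

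The named genes are DNMT1, TP53, CDKN1A, BCL2, BAX, CCNB1 and CDK1 in any case; the 12 genes with the largest rise and the 12 with the largest fall among changed genes whose libraries do not overlap between groups and whose mean over all 8 libraries is at least 5 TPM; and up to 4 changed members of each list with the smallest p. Any other gene named in the text was chosen after its values were seen.

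The fit was first tested on simulated libraries drawn from the mean and the spread within groups of each gene, in which 200 of 13899 genes were changed in each of 5 runs. It recovered 32.8% of genes changed 1.25-fold, 55.2% of those changed 1.5-fold, 90.0% of those changed 2-fold and 96.0% of those changed 4-fold. Unchanged genes made up 5.26% of the calls. Camera called 5 of 5 changed lists and 1 of 100 unchanged lists. In the data 61.1% of tested genes changed, so the adjusted threshold was stricter in the simulation and its shares need not hold for this comparison. Simulated genes were drawn independently, so the list result does not cover lists whose members are correlated.

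The alternatives were upper-quartile scaling, no low-expression filter, a filter of 5 TPM, pseudocounts of 0.1 and 0.01, limma without its trend and robust options, a fit with the replicate number as a block, and each library left out in turn. After the data had been seen, 3 more were added: median-ratio scaling, mitochondrial genes removed, and protein-coding transcripts only. Alternatives planned for read counts were not run because the tables hold TPM. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.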

Results

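Transcript levels were measured by RNA sequencing in MCF-7 breast cancer cells, 4 libraries from untreated cells and 4 from cells exposed to 6 µM 6-thioguanine for 48 h. The series title places the comparison in the setting of apoptosis, the cell cycle and regulation of DNMT1. Libraries of the same group correlated at a Pearson r of 0.984 to 0.987 across genes on the log2 scale, and libraries of different groups at 0.945 to 0.951. The first principal component held 68.8% of the variance and separated the groups. The second held 6.31%, and on it the untreated libraries lay in order of replicate number, at -19.95, -8.61, 11.53 and 17.99. Treated libraries lay between -1.10 and 1.45 on that component. On the third, which held 5.59%, the untreated libraries did not follow that order. The untreated group was thus less uniform on the second component than the treated group, and the cause was not tested. Genes at 1 TPM or more numbered 13450 ± 47.8 (SD, n = 4) in untreated and 14222 ± 83.9 (SD, n = 4) in treated libraries. Mitochondrially encoded transcripts took 19.6% ± 0.626 (SD, n = 4) of the TPM in untreated and 17.8% ± 0.179 (SD, n = 4) in treated libraries.

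DNMT1, the maintenance DNA methyltransferase, was at 117 ± 1.73 TPM (SD, n = 4) in untreated cells and at 58 ± 3.01 TPM (SD, n = 4) after thioguanine, a 2.01-fold difference. The untreated libraries read 116, 115, 116 and 119 TPM, and the treated libraries 58.1, 56.7, 55.1 and 62.1 TPM. The gene (ENSG00000130816.15) lies on the minus strand of chromosome 19 from 10133345 to 10231286 in GRCh38, and the values sum all of its annotated transcripts. The log2 fold change was -0.996, just short of a 2-fold fall on the log2(TPM + 1) scale (SE 0.0425, limma, Benjamini-Hochberg adjusted p = 5.17e-08). The exact two-sided permutation p was 0.0286, the smallest that 4 libraries against 4 can give. Groups did not overlap at 55.5% of all tested genes, and each of these would give the same p. The fall was near the median of the G1/S and replication list, -1.10, so its size was not particular to DNMT1.

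Other genes of the DNA methylation machinery went both ways. UHRF1, which brings DNMT1 to hemimethylated DNA, fell from 43.4 ± 1.94 to 11.3 ± 0.414 TPM (SD, n = 4), and the de novo methyltransferase DNMT3B fell from 14.8 ± 0.764 to 4.15 ± 0.414 TPM (SD, n = 4). HELLS, singled out after its values were seen, fell from 36.6 ± 5.43 to 15.4 ± 1.79 TPM (SD, n = 4). GADD45A, which is also in the list of p53 targets, rose from 7.45 ± 0.897 to 44.2 ± 2.77 TPM (SD, n = 4). GADD45A was the only member of the methylation list to rise at least 2-fold, and 3 members fell at least 2-fold. DNMT3A, singled out after its values were seen, was at 39.0 ± 2.69 TPM without and 43.0 ± 0.662 TPM with the drug (SD, n = 4; limma adjusted p = 0.0504). Of 17 measured members of the list, 4 rose, 7 fell and 6 did not pass the test; adjusted over the list alone, 5 rose and 8 fell. The list as a whole did not pass (camera, direction down, adjusted p = 0.0824, and adjusted p = 0.201 with an estimated correlation). DNMT3L had at most 2.92 TPM in a treated library and DPPA3 was listed at 0 in all 8, so neither was tested.

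**Figure D1:**
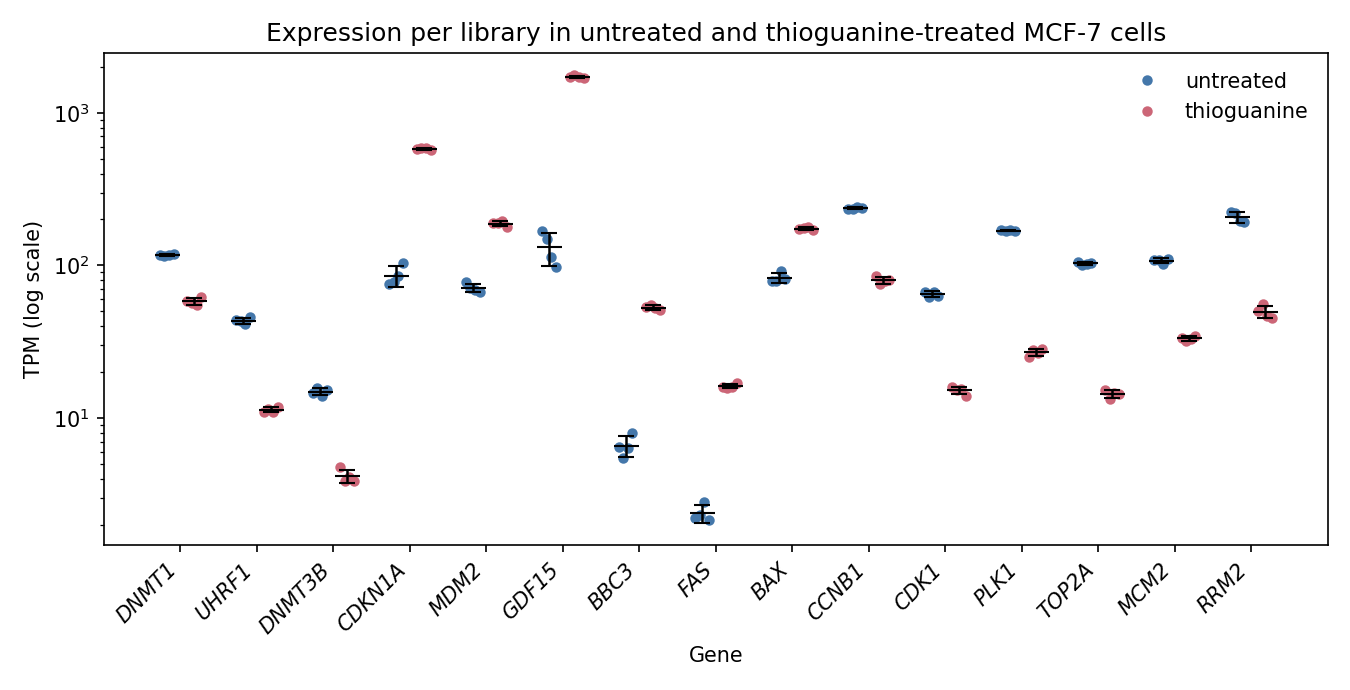
TPM on a log axis for 15 genes, MDM2 among them chosen after its values were seen; each point is a library, horizontal bars are group means and whiskers are SDs over 4 libraries. DNMT1 lies at 115 to 119 TPM in untreated and 55.1 to 62.1 TPM in treated libraries, and in none of the 15 genes do the groups overlap.

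Thioguanine-treated and untreated cells differed at 8486 of 13899 tested genes (limma, Benjamini-Hochberg adjusted p under 0.05), 5346 higher and 3140 lower after treatment. At least 2-fold changes numbered 772 higher and 463 lower. The largest rise on the log2(TPM + 1) scale was of RASD1, a Ras-related GTPase gene induced by dexamethasone. It went from 2.75 ± 0.138 to 49.2 ± 2.82 TPM (SD, n = 4, log2 fold change 3.74). GDF15, a stress-induced cytokine gene, rose from 132 ± 32.4 to 1724 ± 28.4 TPM (SD, n = 4; 3.73), and ACTA2, smooth muscle actin, from 3.53 ± 0.467 to 43.3 ± 2.90 TPM (SD, n = 4; 3.29). The largest falls on that scale were of DLGAP5, a mitotic spindle gene, from 50.2 ± 0.775 to 5.85 ± 0.412 TPM (SD, n = 4, log2 fold change -2.90), and of PCP4. PCP4, which encodes a calmodulin-binding peptide, went from 30.6 ± 6.15 to 3.28 ± 1.00 TPM (SD, n = 4, -2.90). By mean TPM the fall of NR5A2 was larger, 10.8-fold against 9.34-fold for PCP4 and 8.58-fold for DLGAP5.

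The remaining large rises were of IGFBP3 (log2 fold change 2.86), TBX4 (2.86), BBC3 (2.85), NUPR1 (2.83), ALDH3A1 (2.80), CDKN1A (2.76) and AP003419.1 (2.74). AC113404.2 (2.99) and AC131281.1 (2.71) are annotated as pseudogenes, whose reads can come from other copies, so their levels are uncertain. AC113404.2 was at 29.4, 36.1, 0 and 42.6 TPM in the untreated libraries, and its log2 fold change was 1.70 without untreated replicate 3. It did not pass without untreated replicate 1 (limma adjusted p = 0.0528) or without each treated replicate in turn (0.0804 to 0.0995). Its adjusted p was also above 0.05 with the other pseudocounts, among other settings (range over 17 alternatives 1.14e-05 to 0.199). The remaining large falls were of TOP2A (-2.76), PBK (-2.67), ESPL1 (-2.62), PLK1 (-2.61), KIF4A (-2.51), NR5A2 (-2.50), EIF3CL (-2.49), CDCA3 (-2.44), CCNA2 (-2.42) and ANLN (-2.41). EIF3CL is a near-identical copy of EIF3C, which was at 365 ± 61.6 TPM in untreated and 445 ± 9.31 TPM in treated libraries (SD, n = 4), so the split of reads between them is uncertain.

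The balance of higher and lower genes depended on the reference level of each library. Of the changed genes 63.0% were higher on TPM as deposited, 56.4% (4677 higher, 3610 lower) with upper-quartile scaling and 49.5% (4038 higher, 4122 lower) with median-ratio scaling. At least 2-fold changes numbered 667 higher and 532 lower with upper-quartile scaling and 582 higher and 604 lower with median-ratio scaling, so their balance also depended on it. The median log2 fold change of all tested genes was 0.13 on TPM and 0.02 with median-ratio scaling. Medians of gene lists are therefore given below also relative to the median of all genes. Of the 121 named genes, 118 kept their call in every alternative that tested them and none reversed; some were not tested in each of the 18.

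**Figure D2:**
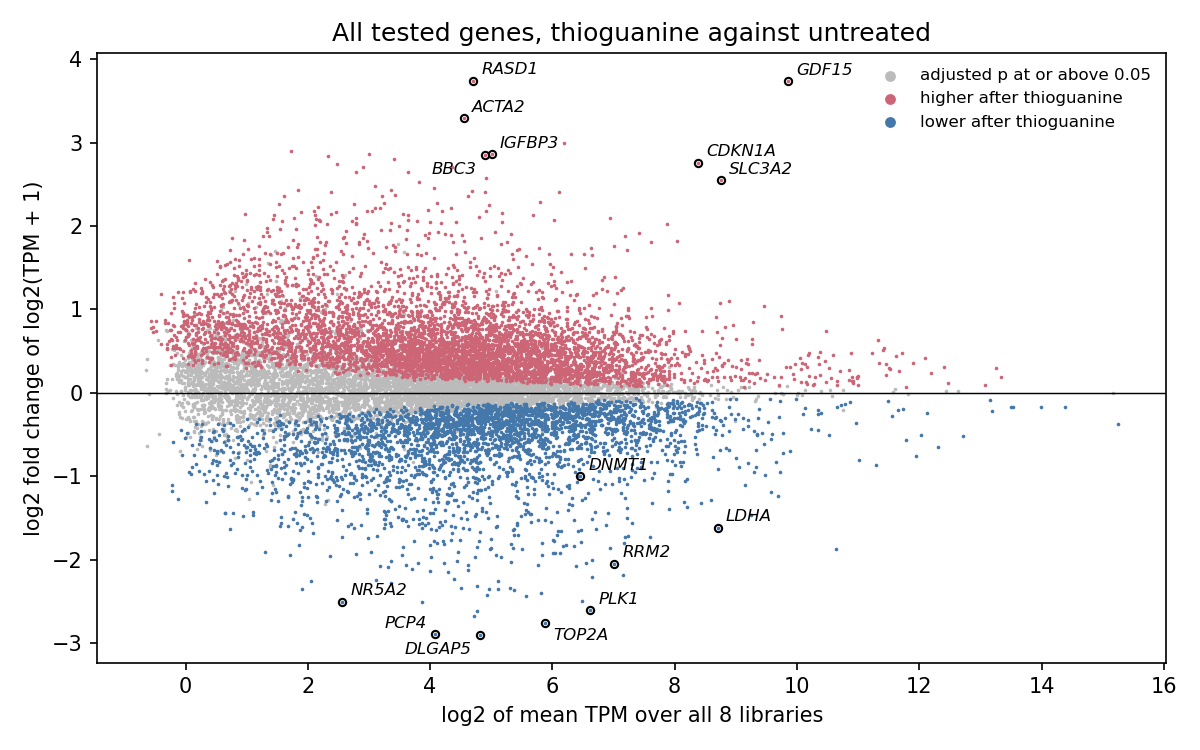
Log2 fold change (thioguanine over untreated, on log2(TPM + 1)) of each of the 13899 tested genes against the log2 of its mean TPM over all 8 libraries, with 15 genes labelled; LDHA was labelled after its values were seen. Colours mark the 5346 higher and 3140 lower genes, with DNMT1 at -0.996, RASD1 at 3.74 and DLGAP5 at -2.90.

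Genes of the G2 phase and mitosis fell together. PLK1, a mitotic kinase, dropped from 169 ± 0.333 to 27.0 ± 1.43 TPM (SD, n = 4), a 6.27-fold fall. TOP2A, which untangles chromosomes, dropped from 103 ± 2.10 to 14.4 ± 0.837 TPM, cyclin B1 (CCNB1) from 237 ± 2.78 to 79.9 ± 3.84 TPM and its kinase CDK1 from 64.9 ± 2.67 to 15.2 ± 0.808 TPM (SD, n = 4 each). Of 38 measured members all 38 fell, over all genes and adjusted over the list alone, 37 of them at least 2-fold. Their median log2 fold change was -1.91, or -2.04 relative to all genes (camera adjusted p = 7.67e-31, and adjusted p = 0.000497 with an estimated correlation).

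Genes of the G1/S transition and DNA replication also fell. The replicative helicase subunit MCM2 fell from 107 ± 3.86 to 33.2 ± 1.09 TPM, MCM6 from 69.5 ± 1.22 to 25.7 ± 1.10 TPM and GINS2, of the same helicase complex, from 50.6 ± 2.95 to 13.2 ± 0.649 TPM (SD, n = 4 each). Of 42 measured members 41 fell, none rose, and RPA2 did not pass over all genes or adjusted over the list alone (log2 fold change -0.12, limma adjusted p = 0.101). The median was -1.10, or -1.23 relative to all genes (camera adjusted p = 1.13e-23, and adjusted p = 0.000888 with an estimated correlation).

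Among the regulators of G1, the kinase inhibitor CDKN1A (p21) rose from 85.6 ± 12.9 to 580 ± 10.1 TPM (SD, n = 4), 6.78-fold, and the pocket protein gene RBL2 rose from 33.7 ± 4.24 to 91.9 ± 5.29 TPM (SD, n = 4). CDK2 fell from 87.1 ± 2.57 to 40.7 ± 2.29 TPM and the inhibitor CDKN2C from 17.8 ± 1.45 to 6.19 ± 0.328 TPM (SD, n = 4 each). Of 17 measured members 6 rose, 9 fell and 2 did not pass, the same counts as adjusted over the list alone. The list did not pass as a whole (camera, down, adjusted p = 0.105, and adjusted p = 0.361 with an estimated correlation). Its median was -0.18, or -0.31 relative to all genes. Its mean (0.08) differed in sign from the median but lay below the median of all genes, 0.13.

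Targets of the tumour suppressor p53 rose together. BTG2, an antiproliferative gene, rose from 24.5 ± 1.64 to 106 ± 2.84 TPM, the decoy death receptor TNFRSF10C from 7.32 ± 0.532 to 41.7 ± 2.10 TPM and PHLDA3, an Akt repressor, from 45.5 ± 2.28 to 154 ± 9.31 TPM (SD, n = 4 each). TP53 itself rose from 150 ± 8.43 to 200 ± 8.61 TPM (SD, n = 4; log2 fold change 0.41). Of 34 measured targets 33 rose, 26 of them at least 2-fold, and 1 fell, with the same counts adjusted over the list alone. The target that fell was PMAIP1, which encodes the pro-apoptotic protein NOXA, from 11.9 ± 0.894 to 8.14 ± 0.831 TPM (SD, n = 4). The median log2 fold change was 1.42, or 1.29 relative to all genes (camera adjusted p = 2.43e-14, and adjusted p = 0.0030 with an estimated correlation).

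**Figure D3:**
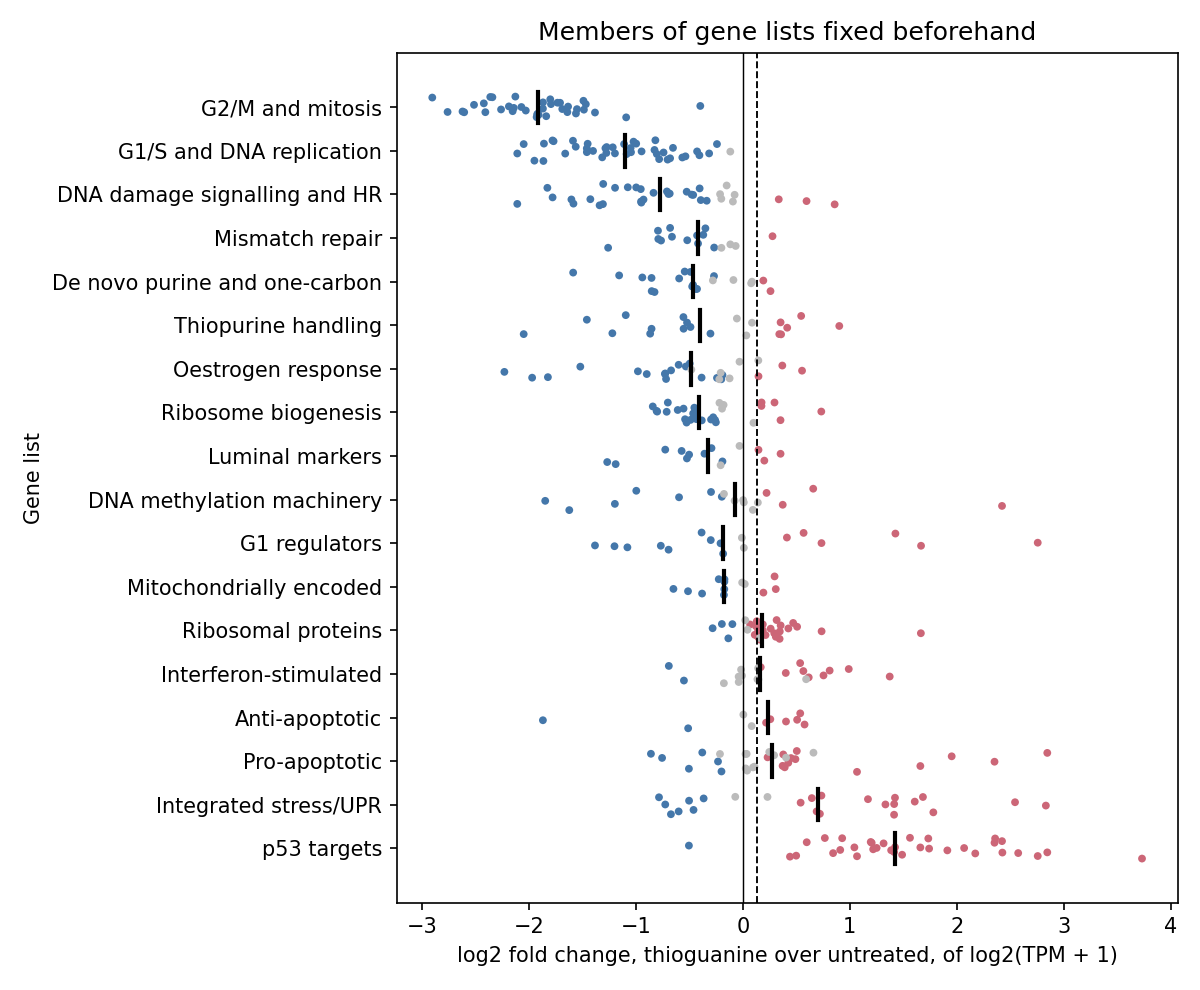
Log2 fold change (thioguanine over untreated) of each measured member of 18 gene lists, with members that passed the test in red (higher) or blue (lower) and the others in grey. Thick bars are list medians and the dashed line is the median of all tested genes, 0.13; the G2/M list has its median at -1.91 and the p53 targets at 1.42, and the median of the ribosomal proteins, 0.18, lies at 0.05 with median-ratio scaling.

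Pro-apoptotic genes that rose included BBC3 (PUMA), from 6.55 ± 1.02 to 53 ± 1.67 TPM, the death receptor FAS, from 2.37 ± 0.312 to 16.2 ± 0.547 TPM, TNFRSF10B, another death receptor, from 29.2 ± 2.20 to 94.5 ± 6.31 TPM, and BAX, from 82.8 ± 6.27 to 174 ± 3.74 TPM (SD, n = 4 each). These 4 are also p53 targets of the list above. Of 30 measured members 13 rose, 6 fell and 11 did not pass, the same counts as adjusted over the list alone. Among those that fell were AIFM1 and CYCS (cytochrome c), chosen after their values were seen, at log2 fold changes of -0.75 and -0.86, and the executioner caspase CASP3, also so chosen, was at 4.35 ± 0.484 and 4.47 ± 0.758 TPM (SD, n = 4). The list did not pass as a whole (camera, up, adjusted p = 0.250, and adjusted p = 0.348 with an estimated correlation).

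Anti-apoptotic genes also moved both ways. BCL2L1 rose from 61.0 ± 3.36 to 88.9 ± 2.07 TPM and MCL1 from 113 ± 2.82 to 150 ± 4.32 TPM, and survivin (BIRC5), which is also a G2/M gene, fell from 71.5 ± 8.12 to 18.8 ± 0.576 TPM (SD, n = 4 each). BCL2 fell from 1.89 ± 0.467 to 1.02 ± 0.232 TPM (SD, n = 4; log2 fold change -0.51, limma adjusted p = 0.0188). Its adjusted p was 0.0515 without untreated replicate 1 and 0.0546 without thioguanine replicate 2 (range over 17 alternatives 0.00245 to 0.0546). Of 10 measured members 6 rose, 2 fell and 2 did not pass, as adjusted over the list alone (camera, up, adjusted p = 0.464, and adjusted p = 0.677 with an estimated correlation).

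Genes of DNA damage signalling and homologous recombination were mostly lower. The histone gene H2AFX fell from 405 ± 6.91 to 164 ± 5.52 TPM, the helicase gene BRIP1 from 111 ± 3.43 to 43.5 ± 3.27 TPM, FANCI of the Fanconi anaemia pathway from 101 ± 3.03 to 29 ± 4.06 TPM and BRCA1 from 33.6 ± 2.36 to 13.0 ± 0.291 TPM (SD, n = 4 each). Of 34 measured members 26 fell, 3 rose (RAD9A, ATM and TP53BP1, named after their values were seen) and 5 did not pass, the same counts as adjusted over the list alone. The median was -0.77, or -0.90 relative to all genes (camera adjusted p = 4.60e-10, and adjusted p = 0.00273 with an estimated correlation).

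Mismatch repair, the pathway that recognises thioguanine mispairs in DNA, was lower as a list. MSH6 fell from 89.0 ± 4.11 to 51.0 ± 0.907 TPM, its partner MSH2 from 34.5 ± 0.519 to 19.5 ± 1.24 TPM and the exonuclease EXO1 from 19.2 ± 0.905 to 7.48 ± 1.10 TPM (SD, n = 4 each). Of 16 measured members 12 fell, PMS2 (named after its values were seen) rose and 3 did not pass; adjusted over the list alone, 13 fell and 1 rose. The median was -0.42, or -0.55 relative to all genes (camera adjusted p = 4.49e-06, and adjusted p = 0.0220 with an estimated correlation). PCNA, LIG1 and RPA2 of this list also belong to the replication list, and PMS2 did not pass with median-ratio scaling, where none of the members rose and 14 fell.

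Genes for the uptake, activation, inactivation or efflux of thiopurines went both ways, and more fell than rose. HPRT1, which converts 6-thioguanine to its nucleotide, fell from 86.5 ± 11.1 to 36.3 ± 0.429 TPM, and the nucleoside transporter SLC29A1 from 55.8 ± 1.47 to 25.6 ± 0.515 TPM (SD, n = 4 each). RRM2, the ribonucleotide reductase subunit shared with the replication list, fell from 208 ± 17.2 to 49.5 ± 4.59 TPM (SD, n = 4). The inactivating enzymes TPMT and NUDT15, chosen after their values were seen, had log2 fold changes of -0.52 and -0.56. The members that rose, also named after their values were seen, were NT5E (0.90), NT5C (0.42), ITPA (0.36) and the efflux genes ABCC5 (0.55), ABCC4 (0.35) and ABCG2 (0.34). Of 20 measured members 11 fell, 6 rose and 3 did not pass, as adjusted over the list alone (median -0.40, or -0.53 relative to all genes; camera adjusted p = 0.00854, but adjusted p = 0.0814 with an estimated correlation).

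De novo purine synthesis and one-carbon genes showed a similar direction. MTHFD1 fell from 177 ± 5.81 to 58.5 ± 5.33 TPM, SHMT1 from 94.4 ± 3.46 to 41.8 ± 1.55 TPM and PAICS from 143 ± 10.4 to 73.9 ± 4.64 TPM (SD, n = 4 each). Of 20 measured members 14 fell, 2 rose (MTHFD2 and SHMT2, named after their values were seen) and 4 did not pass; adjusted over the list alone, 15 fell and 2 rose. With median-ratio scaling neither of the 2 passed. The median was -0.47, or -0.60 relative to all genes (camera adjusted p = 7.81e-06, but adjusted p = 0.104 with an estimated correlation).

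The integrated stress and unfolded protein response list split. SLC3A2, an amino acid transporter subunit, rose from 126 ± 11.5 to 736 ± 3.59 TPM, the transcription factor ATF4 from 216 ± 7.16 to 360 ± 6.88 TPM and PPP1R15A, a feedback regulator of the integrated stress response, from 14.4 ± 0.776 to 40.0 ± 2.54 TPM (SD, n = 4 each). Of 24 measured members 15 rose, 7 fell and 2 did not pass, as adjusted over the list alone (camera, up, adjusted p = 0.105, and adjusted p = 0.546 with an estimated correlation). Among the 7, named after their values were seen, were SDF2L1 (log2 fold change -0.78), XBP1 (-0.73), PDIA4 (-0.67), HSP90B1 (-0.50) and CALR (-0.46). The list passed with median-ratio scaling (adjusted p = 0.0366; range over 18 alternatives 0.0366 to 0.186).

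Most oestrogen-induced genes were lower, but the list did not pass with an estimated correlation. The progesterone receptor gene PGR fell from 35.3 ± 5.73 to 6.68 ± 0.553 TPM, CA12 from 117 ± 12.1 to 32.3 ± 3.01 TPM and RET from 43.0 ± 6.03 to 10.2 ± 1.08 TPM (SD, n = 4 each). The receptor gene ESR1, chosen after its values were seen, fell from 101 ± 5.17 to 88.7 ± 8.67 TPM (SD, n = 4; limma adjusted p = 0.0364). Of 26 measured members 17 fell, 3 rose (NRIP1, FOXA1 and PDZK1, also named after their values were seen) and 6 did not pass; adjusted over the list alone, 18 fell and 3 rose. The median was -0.49, or -0.62 relative to all genes (camera adjusted p = 5.54e-06, but adjusted p = 0.168 with an estimated correlation), and with median-ratio scaling 1 of the 26 rose and 21 fell.

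Luminal markers shared some of these genes. MUC1 fell from 206 ± 7.60 to 85.2 ± 6.82 TPM, SPDEF from 98.4 ± 2.43 to 42.6 ± 1.63 TPM and keratin 8 (KRT8) from 7965 ± 707 to 5529 ± 62.9 TPM (SD, n = 4 each). Of 14 measured members 9 fell, 3 rose and 2 did not pass, as adjusted over the list alone (median -0.33, or -0.46 relative to all genes; camera adjusted p = 0.000949, but adjusted p = 0.168 with an estimated correlation). Of 7 measured basal or mesenchymal markers, 2 rose (SNAI2 and TP63), 2 fell (COL3A1 and FN1) and 3 did not pass, as adjusted over the list alone. SNAI2 was at most 0.324 TPM in untreated libraries. It passed the filter only through the treated ones, so it could only come out as a rise. Their median (0.02) and mean (0.10) were positive, but the median was -0.11 relative to all genes and -0.05 with median-ratio scaling. Camera, which compares members with other genes, gave the direction down (adjusted p = 0.586, and adjusted p = 0.619 with an estimated correlation). FN1 did not pass without untreated replicate 1, untreated replicate 3 or thioguanine replicate 4, at adjusted p-values of 0.0530, 0.0542 and 0.0513 (range over 18 alternatives 5.32e-07 to 0.0542).

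Of 14 blood and endothelial markers 3 were measured, the others being below the filter. All 3 rose, as adjusted over the list alone: CD68 from 2.65 ± 0.599 to 7.05 ± 0.828 TPM, CDH5 from 0.275 ± 0.195 to 1.96 ± 0.384 TPM and HBA1 from 5.16 ± 1.47 to 9.74 ± 2.35 TPM (SD, n = 4 each). CDH5 passed the filter only through the treated libraries, so it could only come out as a rise. The list did not pass (camera, up, adjusted p = 0.105, and adjusted p = 0.243 with an estimated correlation).

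Interferon-stimulated genes and NF-kappaB targets had members that rose. IRF9 rose from 25.2 ± 1.99 to 67.0 ± 4.29 TPM and STAT2 from 21.2 ± 1.10 to 43.2 ± 1.83 TPM (SD, n = 4 each). Of 20 measured interferon genes 9 rose, 2 fell and 9 did not pass, and adjusted over the list alone 8 rose and 2 fell. Over all tested genes 5346 of 13899 rose. The interferon median was 0.16, or 0.03 relative to all genes (camera, up, adjusted p = 0.254, and adjusted p = 0.419 with an estimated correlation). Of 12 measured inflammatory secretory genes 7 rose, 1 (TNFAIP2, named after its values were seen) fell and 4 did not pass, as adjusted over the list alone, with NFKBIA going from 145 ± 7.02 to 230 ± 8.22 TPM (SD, n = 4; camera, up, adjusted p = 0.109, and adjusted p = 0.361 with an estimated correlation). The 29 cancer-testis genes, which promoter methylation commonly silences, were all below 1 TPM in every library, so none was tested.

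Most ribosome biogenesis genes fell and most ribosomal protein genes rose on TPM as deposited, but neither list passed with an estimated correlation. Nucleolin (NCL) fell from 757 ± 47.8 to 422 ± 22.8 TPM and NOP58 from 127 ± 7.15 to 77.2 ± 3.30 TPM, and NOB1 rose from 72.7 ± 1.48 to 122 ± 3.71 TPM (SD, n = 4 each). Of 28 measured biogenesis genes 19 fell, 5 rose and 4 did not pass; adjusted over the list alone, 21 fell and 5 rose, and with median-ratio scaling 22 fell and 2 rose (median -0.41, or -0.54 relative to all genes; camera adjusted p = 1.06e-05, but adjusted p = 0.168 with an estimated correlation). RPS19 rose from 1064 ± 52.5 to 1773 ± 63.4 TPM and RPLP0 from 2251 ± 65.3 to 3200 ± 37.8 TPM (SD, n = 4 each). Of 33 measured ribosomal protein genes 26 rose, 4 fell and 3 did not pass; adjusted over the list alone, 27 rose and 4 fell (median 0.18, or 0.05 relative to all genes; camera adjusted p = 0.000161, but adjusted p = 0.356 with an estimated correlation). With median-ratio scaling 13 of the 33 rose and 6 fell, and the list did not pass (adjusted p = 0.0654; range over 18 alternatives 6.91e-06 to 0.0654).

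Hypoxia and glycolysis genes went both ways. ENO1 fell from 1112 ± 80.9 to 575 ± 12 TPM and GAPDH from 4976 ± 421 to 2944 ± 36.8 TPM, and PFKFB3, whose product activates phosphofructokinase, rose from 37.2 ± 1.97 to 72.6 ± 3.78 TPM (SD, n = 4 each). Of 24 measured hypoxia and glycolysis genes 12 fell, 6 rose and 6 did not pass, as adjusted over the list alone (median -0.29, or -0.43 relative to all genes; camera adjusted p = 0.0292, but adjusted p = 0.519 with an estimated correlation). That list also did not pass with median-ratio scaling (adjusted p = 0.0654) or with protein-coding transcripts only (adjusted p = 0.0677; range over 18 alternatives 0.00727 to 0.0677). Of 26 nuclear-encoded respiratory chain genes 15 fell, 4 rose and 7 did not pass, as adjusted over the list alone, and with median-ratio scaling 18 fell and 1 rose, with NDUFS1 going from 41.1 ± 2.05 to 26.1 ± 0.974 TPM (SD, n = 4; median -0.21, or -0.34 relative to all genes; camera adjusted p = 0.000298, but adjusted p = 0.243 with an estimated correlation).

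Of 13 mitochondrially encoded mRNAs 8 fell, 3 rose and 2 did not pass, as adjusted over the list alone (median -0.17, or -0.30 relative to all genes; camera adjusted p = 0.00854, but adjusted p = 0.250 with an estimated correlation). MT-ND1 fell from 6204 ± 168 to 3956 ± 63.0 TPM and MT-ND2 from 4933 ± 180 to 3457 ± 54.1 TPM (SD, n = 4 each). MT-ATP6, MT-ATP8 and MT-CO3, named after their values were seen, had log2 fold changes of 0.31, 0.30 and 0.19, and 1 of the 13 rose with median-ratio scaling. The list did not pass with protein-coding transcripts only (adjusted p = 0.0788; range over 17 alternatives 0.0026 to 0.0788).

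Replication-dependent histone genes, cholesterol genes and reference genes completed the lists. HIST2H2AC fell from 58.4 ± 4.96 to 11 ± 3.49 TPM and HIST1H3B from 19.2 ± 3.81 to 5.63 ± 0.964 TPM (SD, n = 4 each). Of 21 measured histone genes 10 fell, 5 rose and 6 did not pass, as adjusted over the list alone, and with median-ratio scaling 10 fell and 3 rose. The median (0.003, or -0.13 relative to all genes) and mean (-0.30) differed in sign, with camera's direction down (adjusted p = 0.0346, but adjusted p = 0.380 with an estimated correlation). The histone list failed in 5 of 18 alternatives, among them without untreated replicate 4 (adjusted p = 0.116) and with median-ratio scaling, where its median was -0.11 (adjusted p = 0.0694; range 0.00338 to 0.154). Of 26 measured cholesterol genes 12 fell, 3 rose and 11 did not pass, as adjusted over the list alone, with EBP going from 105 ± 4.49 to 56.8 ± 2.23 TPM (SD, n = 4; median -0.16, or -0.30 relative to all genes; camera adjusted p = 0.00911, but adjusted p = 0.455 with an estimated correlation). Of 14 commonly used reference genes 8 fell, 2 rose and 4 did not pass, as adjusted over the list alone. With upper-quartile and with median-ratio scaling 10 of them fell and 1 rose. Their median was -0.18, or -0.31 relative to all genes (camera adjusted p = 0.0046, but adjusted p = 0.0814 with an estimated correlation). PPIA, a common reference, fell from 3249 ± 52.3 to 1776 ± 24.3 TPM (SD, n = 4).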

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

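No explanation was tested for the single libraries described below. In each group of 4 libraries, a library counted as far from the others when its gap to the nearest exceeded, as a share of the group's range, Dixon's 95% critical value for 4 samples. This was met in 12 of 260 groups examined, and chance alone gives about 5% of groups. The rule looks for single libraries and does not detect a steady shift with replicate number. No second contrast and no data outside the comparison gave a further result.

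AP003419.1, among the genes with the largest rise, was at 1.15 TPM in untreated replicate 4 against 0.522 to 0.567 TPM in the other untreated libraries. In thioguanine replicate 4 it was at 6.94 TPM against 11.3 to 11.9 TPM in the other treated libraries, so both groups had replicate 4 nearest to the opposite group. The endothelial marker CDH5 was at 0.565 TPM in untreated replicate 4 against 0.155 to 0.213 TPM. HPRT1 was at 70.1 TPM in that library against 89.6 to 93.4 TPM. MT-ND5 was at 9666 TPM there against 10160 to 10252 TPM.

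EXO1 was at 17.8 TPM in untreated replicate 2 against 19.5 to 19.7 TPM in the other untreated libraries. FAS was at 17.0 TPM in thioguanine replicate 4 against 15.8 to 16 TPM. ICAM1 was at 15.0 TPM in thioguanine replicate 2 against 11.1 to 11.6 TPM. MSH2 was at 21.4 TPM in thioguanine replicate 3 against 18.7 to 19.0 TPM. PHLDA3 was at 42.1 TPM in untreated replicate 3 against 46.3 to 47.0 TPM, and SPDEF was at 102 TPM in untreated replicate 1 against 96.8 to 97.6 TPM. SPARC, named after its values were seen and below the filter for testing, was at 72.5 TPM in untreated replicate 3 against 0.289 to 2.22 TPM in the other untreated libraries and at most 0.842 TPM in treated libraries. Each of these genes other than SPARC passed the comparison of treated with untreated cells.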

How the results depend on the processing

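Median-ratio scaling, removal of mitochondrial genes and protein-coding transcripts only were chosen after the data were seen; the other alternatives were fixed before. DNMT1 kept its fall, from -1.18 with protein-coding transcripts only to -0.97 without thioguanine replicate 3. Changed genes numbered 7778 to 8211 with each library left out in turn, 4761 to 5196 of them higher and 2945 to 3017 lower, against 8486 with all libraries. Genes at least 2-fold higher numbered 772, but 510 with a filter of 5 TPM, which tests fewer genes, and 1178 and 1214 with pseudocounts of 0.1 and 0.01, which shrink low genes less. Over all alternatives, counts of genes stayed within 1.5-fold in 87 cases and moved in these 3. For single named genes, 2134 calls stayed and 16 were lost, all of AC113404.2, BCL2 and FN1, and none reversed; an alternative that did not test a gene gives no result for it. CDH5, IRF7, NUPR1 and SNAI2 reached 1 TPM only in treated libraries, so they could only come out as rises. These genes were not tested with any treated library left out.

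Lists past the threshold fell from 17 to 5 with an estimated correlation. The DNA methylation list passed without the low-expression filter (adjusted p = 0.0425, range over 18 alternatives 0.0425 to 0.158) and with fry (8.44e-06). Fry, which asks only whether members move on balance, also called the pro-apoptotic list (1.87e-07), the G1 regulators (0.00381), the integrated stress and unfolded protein response list (4.10e-05), the interferon list (4.10e-05), the inflammatory secretory list (4.34e-05) and the blood or endothelial markers (4.61e-05). It did not call the cholesterol list (0.0750). Of all list results, 502 stayed, 22 lost their call and 9 gained it; other than for fry and the estimated correlation, the cause was not tested. With median-ratio scaling fewer members rose than on TPM: 10 rather than 13 pro-apoptotic, 4 rather than 6 anti-apoptotic, 4 rather than 6 thiopurine and 7 rather than 9 interferon genes. Equal replicate numbers did not pair libraries, since their deviations from the group means correlated at -0.016 to 0.007, and a replicate block gave 8266 changed genes. The alternatives planned for read counts were not run because the tables hold TPM. Depth is unknown, so a limit it sets on low genes cannot be given. In simulated data the fit recovered 55.2% of 1.5-fold changes, but far fewer genes were changed there, so that share need not hold here.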

Other observations

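The tests of the share of MCF-7 cells, of the mitochondrial share, of scaling (by median-ratio scaling, in both patterns), of precursor RNA and of gene length were chosen only after the results they bear on were seen, as were the genes of the next paragraph; the other tests were not.

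Some genes known to be induced through the aryl hydrocarbon receptor were among those higher after thioguanine. CYP1A1 rose from 2.96 ± 1.65 to 22.0 ± 1.63 TPM (SD, n = 4; log2 fold change 2.65), AHRR, the repressor of the receptor, from 4.10 ± 1.26 to 20.9 ± 2.18 TPM (2.14) and the receptor gene AHR from 16.6 ± 2.01 to 43.2 ± 2.57 TPM (1.34). The detoxification genes ALDH3A1 and UGT1A6 rose by 2.80 and 1.34 on the log2 scale, CYP1B1 by 0.64, NQO1 by 0.34 and TIPARP by 0.27. All 8 passed the test over all genes, but they were picked because they looked high, so their number shows nothing about the pathway.

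Some autophagy genes were also higher. SQSTM1, an autophagy receptor gene, went from 301 ± 16.6 to 648 ± 53.1 TPM and MAP1LC3B, of the autophagosome membrane, from 36.4 ± 1.94 to 89.6 ± 4.97 TPM (SD, n = 4 each; log2 fold changes 1.10 and 1.28). From these and 4 others a hypothesis was formed that autophagy genes rise as a group, and it was tested on 36 further members whose values had not been seen. Of these 26 rose and 2 fell, with WDR45 going from 25.5 ± 2.20 to 76.2 ± 1.47 TPM and ATG13 from 49.5 ± 3.47 to 102 ± 3.68 TPM (SD, n = 4 each). Camera gave p = 3.91e-05 in the upward direction and p = 0.0687 with an estimated correlation, so the call depends on the correlation assumed, and a coordinated rise of autophagy genes may be taken only as a hypothesis. The median log2 fold change was 0.52, or 0.39 relative to all genes.

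The fall of replication and G2/M genes with the rise of p53 targets was set against 3 technical explanations. After the GC trend of each library was removed, 100% of the 113 called members of the 3 lists kept their call and direction. So did 100% under median-ratio scaling. These shares alone could not decide, because both corrections were small beside the list medians of -1.91, -1.10 and 1.42. Over groups of genes by GC content the median log2 fold change was 0.008 to 0.21. Median-ratio scaling moved the median of all genes from 0.13 to 0.02. The small size of these shifts argues against GC content and scaling as the whole cause. A lower share of MCF-7 cells alone would lower luminal markers at least about as much as the G2/M genes. The medians of these lists were -0.33 and -1.91, which argues against it as the whole cause. A smaller loss of MCF-7 cells stays open, since 9 of 14 luminal markers fell. An effect of the drug on the cell cycle and on p53 may underlie the pattern, as a hypothesis found and tested on the same libraries. An effect of a vehicle, which the labels do not name, or of differences between cultures cannot be told apart from it.

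More genes were higher than lower after thioguanine. The lower share of mitochondrial transcripts in treated libraries is argued against as the whole cause, since 60.3% of changed genes were still higher with those genes removed. With median-ratio scaling 49.5% were higher, but that scaling centres the genes and so fixes its own outcome. Whether the excess comes from the cells or from scaling to a fixed sum cannot be told apart, because the tables hold no amount of RNA per cell. The drug itself stays open as a cause that these values cannot test.

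Retained-intron transcripts rose against coding transcripts of the same gene by a median log2 change of 0.33 over 4125 genes, in 73.1% of them. The rise was not particular to them: those annotated as processed transcripts rose likewise by 0.357 over 3664 genes, in 72.05% of them. The two-sided permutation p on the library medians of the retained-intron ratio was 0.0286, the smallest possible with 4 against 4. Each gene was first centred on its untreated mean, which can favour the real split, so this p is not exact. In the 1086 genes with at least 10 TPM of retained-intron transcripts in untreated cells the median change was 0.206. An even background of genomic DNA is argued against by 6410 coding genes under 0.5 TPM in untreated cells, which rose by a median of 0.00835 TPM where retained-intron transcripts exceeded prediction by 1.08 TPM. More precursor RNA as the only cause is argued against by spliced transcripts annotated for nonsense-mediated decay, which rose by 0.44. The estimation spreading reads over shorter transcripts stays open, since short coding transcripts rose by 0.207 against the longest of their gene. Treated libraries had more transcripts above 0 TPM, 97296 ± 510 against 88954 ± 599 in untreated ones (SD, n = 4 each). Depth is unknown, so a difference in depth between the groups could not be tested and also stays open. Weaker nonsense-mediated decay could also contribute: of 10 genes of its machinery that rise by feedback 7 rose (camera p = 0.0179, and p = 0.117 with an estimated correlation), led by SMG5 at a log2 fold change of 0.80.

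A hypothesis that longer genes fall more was not borne out: over 12804 coding genes the Spearman rho of log2 fold change on genomic span was -0.031, where genes are not independent replicates. Of the 35 ways to split the 8 libraries into groups of 4, only 1, the real one, gave as many changed genes (8486, the highest other 2). It was also the only 1 to give as many higher (5346, other 2) or lower (3140, other 1). The same held for genes at least 2-fold higher (772, other 2) or lower (463, other 1). An accidental grouping of these libraries is thus an unlikely source of these counts. It is not excluded, since 1 of 35 is the smallest share possible. Every other split mixes the groups, which widens the spread within them and lowers its count. If the libraries of a group came from a single culture, the splits do not address differences between cultures. For the number of gene lists past the threshold, 5 of 35 splits gave at least the real 17, the highest other being 18, so chance cannot be excluded for that count. Those other splits keep 3 of the 4 libraries of each group together and so carry part of the difference between the groups; the splits with 2 libraries of each group on either side called 0 to 4 lists.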
